A study of Homo sapiens with 8 samples.

How the data were processed

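RNA sequencing of 8 libraries was analysed. Per the labels, these are HCT116 cells with intact or knocked-out MTF1, 1 cultured library each, and 3 tumours per genotype after injection into NSG mice. The design text gives 24 days, without saying whether this is the age of the tumours or of the mice. Per the labels' protocols, RNA came from Trizol for tumours and from a column kit for cells, so the setting and the extraction go together. Per the submitters' processing notes, bcl2fastq 2.17.1.14, cutadapt, HISAT2 2.0.1, StringTie 1.3.3b and Cufflinks 2.2.1 were used, with no role given for each. The genome build, annotation release, counting program and strand setting are not given in the sources used here, nor is any step that separates mouse from human reads.

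One table held all values for 60612 genes. The deposited raw counts are whole numbers, 1 column per library, with 0 columns left unmatched to a sample. The deposited FPKM values were made by the authors, per the file headers, and equal the count scaled by the exonic size and by the total gene count of the library, within rounding to 2 decimals, in 100% of values. Of the gene IDs, 58394 (96.3%) were found in GENCODE 29 (GRCh38), 100% of these on the same chromosome, 77.0% with the same start and end and 92.1% with the same start or end. Coordinates are printed as the table gives them. GC content was taken from that annotation and genome. The 1079 entries that share a symbol or lack one were kept in the fits and left out of the naming.

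Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on the counts, with TMM scaling, two-sided, at a Benjamini-Hochberg adjusted p of 0.05. The standard error is the size of the log2 fold change divided by the square root of F. Tumours of the 2 genotypes were compared with the 6 tumours alone, for genes with an FPKM of at least 1 in at least 3 libraries (4 residual degrees of freedom, biological coefficient of variation 18.9%). Tumours were compared with culture over 8 libraries with genotype as a term, for genes with an FPKM of at least 1 in at least 2 libraries (5 residual degrees of freedom, 20.5%). The difference of the knockout effect between the settings was a contrast of the 4 group means (4 residual degrees of freedom). The last 2 had been planned as limma on FPKM values. Once counts were seen, edgeR replaced it, a departure from the plan, and limma on log2(FPKM + 1) was kept as an alternative (2638 genes for tumours against culture and 1 for the interaction). With 1 cultured library per genotype, the cultured difference of log2(FPKM + 1) has no test, and lists are placed by the percentile of their median among 10000 random lists matched on size and level.

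The comparisons, 41 gene lists and the rule for named genes were fixed before the data were examined. The lists of immediate early genes, ribosomal proteins, histones and mitochondrially encoded genes were set then as quality lists, not as pathways. Lists with at least 5 measured members were tested with camera of limma 3.58.1, at a preset correlation of 0.01 and with an estimated correlation, and with fry, on log2 CPM. Members were also adjusted over the list alone. Named genes were MTF1, the measured metallothioneins, and, among genes past the threshold with a mean FPKM of at least 2 in the higher group and groups that do not overlap, the 12 with the largest rise and the 12 with the largest fall of log2(FPKM + 1). For the cultured cells these were 10 each way at an FPKM of at least 5, for the interaction the 3 smallest p each way, and for a list up to 4 members. Genes named outside this rule were chosen after their values were seen, as with chromosome 12.

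The scripts were tested on simulated data made from the means and sizes of these libraries. For the tumour comparison (13617 genes), 8.96% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 87.9% of those changed 4-fold were recovered, with 10 false among 117 calls. For tumours against culture (14720 genes) these were 5.97%, 47.8% and 90.9% (5 of 101), and for the interaction (14720 genes) 1.49%, 1.49% and 51.5% (5 of 41).

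Totals ranged from 10689490 to 16298595 counts per library. A group at 0 counts was given a floor of 3 counts over the group, and ratios with 1 to 3 counts have a 95% Clopper-Pearson interval. Alternatives were other pseudocounts and filters, TPM, median-of-ratios, quantile and library-total scaling, robust fits, voom with library quality weights, limma on FPKM, DESeq2 1.42.0, a replicate block, each library left out in turn, and the tests without chromosome 12. DESeq2, library totals, the fit without chromosome 12, the test of 4 metallothioneins and TMM in the cultured cells were chosen after the data were seen. Reads, splicing and variants were not analysed here.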

Results

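HCT116 is an established human colon carcinoma line. MTF1 encodes a zinc-sensing transcription factor that switches on metallothionein genes, whose small proteins bind zinc, copper and cadmium. RNA was sequenced from 1 cultured wild-type (WT) library, 1 cultured MTF1-knockout (KO) library, and 3 tumours per genotype grown from these cells in NSG mice, an immunodeficient strain. The table lists 60612 human genes. Total gene counts were 16298595 in WT cells and 16061589 in KO cells, 13997867 to 15280855 in the WT tumours, and 10689490 to 15625404 in the KO tumours. The labels name the tumours of a genotype as replicates. All 6 pairs of tumours within a genotype differed by more than sampling noise (chi-square per degree of freedom 10.9 to 47.5), which argues against 1 library sequenced again. Each tumour was counted as 1 sample, though the design text does not say whether each came from its own mouse. KO tumour 2 lay apart from the rest. It had 11919 genes at an FPKM of at least 1, against 13618 to 14023 in the other tumours, and long non-coding RNA took 0.954% of its counts, against 1.45% to 1.62%. On the first principal component (46.1% of the variance of the tumours) it lay at 49.8, and the others between -24.3 and 4.45. It was also the tumour nearest to the cultured cells, with a correlation across genes of 0.945 and 0.948 with the WT and KO cells, against 0.916 to 0.936 for the other tumours, and the cells had 12129 and 12432 genes at an FPKM of at least 1.

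The targeted gene was still transcribed in each KO library. MTF1 (ENSG00000188786, chromosome 1, 37809574 to 37859592) had an FPKM of 6.94 in WT cells and 4.90 in KO cells. The WT tumours had 3.93, 4.29 and 4.50 (4.24 ± 0.288, SD, n = 3), and the KO tumours 3.95, 2.86 and 3.86 (3.56 ± 0.605). The tumour difference did not pass edgeR's quasi-likelihood test (log2 fold change -0.23, SE 0.14, Benjamini-Hochberg adjusted p = 0.342). A disrupted gene can keep its transcript, so these values do not check the knockout.

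Metallothioneins, the best known MTF1 targets, were asked about first. MT2A, MT1E and MT1F were lower in the cultured KO library than in the WT library, and MT1X was not (FPKM 6.06 against 5.79). MT2A (ENSG00000125148), the most abundant member, had an FPKM of 231 in WT cells and 126 in KO cells, and MT1E 116 and 65.9. In the tumours 0 members were called lower, though the difference between the settings did not pass either (edgeR interaction, MT2A adjusted p = 0.296, MT1E 0.379). MT2A was at 321 ± 53.1 in WT and 473 ± 148 in KO tumours (SD, n = 3 each), MT1E at 131 ± 6.52 and 151 ± 33.4, MT1X at 18.3 ± 2.80 and 21.7 ± 7.53, and MT1F at 3.21 ± 0.690 and 3.16 ± 0.603. MT1A, MT1G, MT1H, MT1M, MT3 and MT4 were listed at 0 in each of the 8 libraries, and MT1B reached at most 0.24. Of 4 members tested in the tumours, 0 passed edgeR's quasi-likelihood test and 1 was at an unadjusted p under 0.05. The log2 fold change was 0.58 for MT2A (SE 0.22, adjusted p = 0.138, and 0.104 adjusted over the list alone), 0.24 for MT1E (adjusted p = 0.448), 0.28 for MT1X (adjusted p = 0.510) and 0.02 for MT1F (adjusted p = 0.973), and the sign for MT1E and MT1F turned under other scalings. Summed over the family, the WT tumours had 465 ± 76.7 CPM (counts scaled to the library total) and the KO tumours 640 ± 163, a difference that did not pass a two-sided exact permutation test (p = 0.2, with 0.1 the smallest that 3 against 3 can give). The members are close copies, so the split of reads between them is uncertain. The sum does not depend on that split. It would depend on reads that were discarded or assigned outside the family, and the counting program is not given.

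Few other metal genes differed between the genotypes. SLC30A1, a zinc exporter known as an MTF1 target, was at an FPKM of 10.5 ± 0.953 in WT and 8.10 ± 1.42 in KO tumours (edgeR, adjusted p = 0.241). Of 18 zinc transporters measured, SLC39A8, an importer of zinc and manganese, rose in KO tumours (log2 0.64, adjusted p = 0.0483), and SLC39A7, which releases zinc from the endoplasmic reticulum, fell by 0.54 (adjusted p = 0.0375). SLC39A7 was also lower in the cultured KO library (96.0 in WT, 56.0 in KO). Of 20 copper genes, the mitochondrial copper chaperone COX17 rose (log2 0.67, adjusted p = 0.0335, and 2 members rose adjusted over the list alone). Of 16 iron genes 0 passed edgeR's test, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. None of these lists moved as a set (camera, adjusted p 0.595 for zinc, 0.165 for copper and 0.655 for iron).

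**Figure D1:**
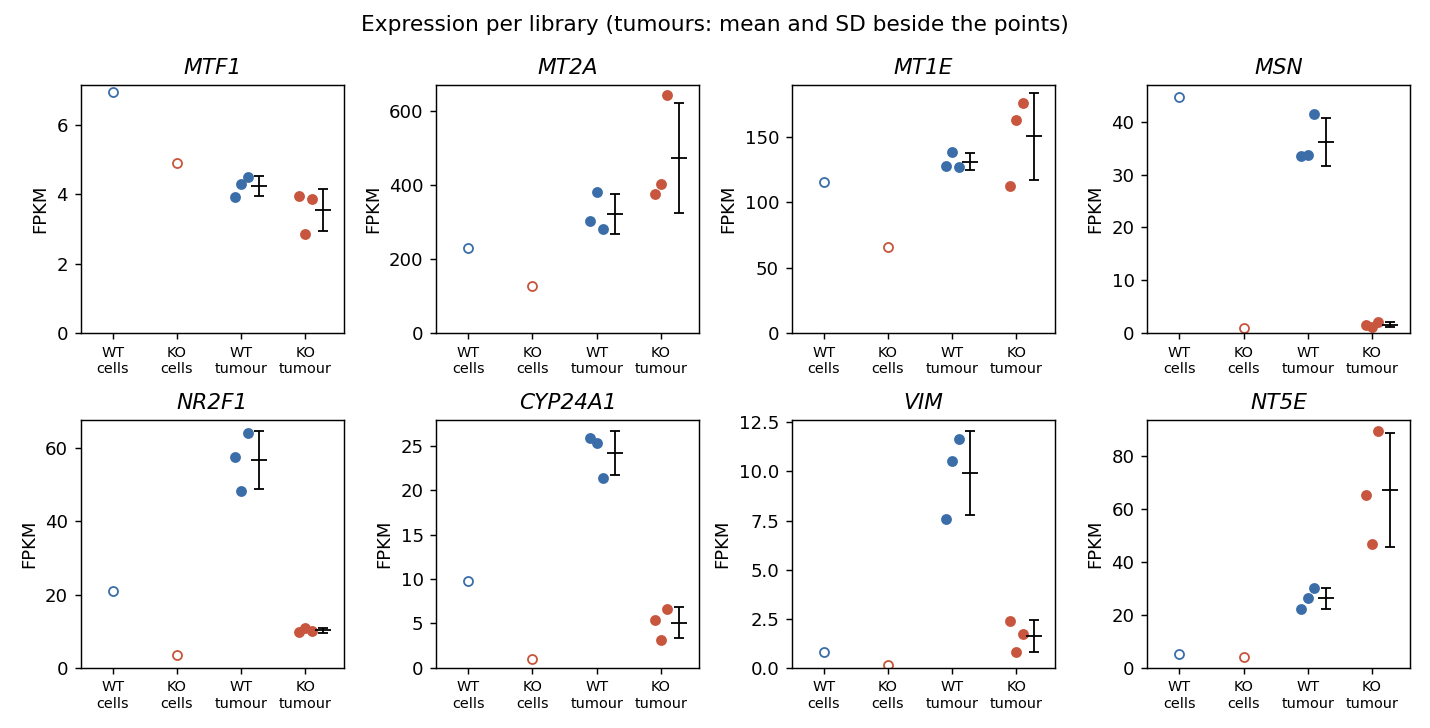
FPKM of MTF1, MT2A, MT1E, MSN, NR2F1, CYP24A1, VIM and NT5E in each of the 8 libraries, 1 point per library, with the mean and SD of each tumour group (n = 3). MSN lay at 36.2 ± 4.51 in the WT tumours and at 1.59 ± 0.471 in the KO tumours, while the MT2A values of the KO tumours (374 to 643) overlapped those of the WT tumours (281 to 382).

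The tumour comparison asked which genes differ between MTF1-KO and WT tumours of 1 line. With 1 KO line, the p-values measure the spread between tumours and not between independent knockouts. Another difference between the WT and KO populations therefore cannot be separated from MTF1 loss, in any gene or list below. Moesin, which ties actin filaments to the cell membrane, was 22.3-fold lower in KO tumours (MSN, ENSG00000147065, chromosome X, 65588377 to 65741931), with an FPKM of 36.2 ± 4.51 in WT and 1.59 ± 0.471 in KO (SD, n = 3 each). NR2F1, a nuclear receptor of dormant and developing cells, fell from 56.7 ± 7.97 to 10.2 ± 0.661. CYP24A1, the enzyme that degrades vitamin D, fell from 24.2 ± 2.47 to 5.06 ± 1.75, and vimentin (VIM), a filament protein of mesenchymal cells, from 9.92 ± 2.12 to 1.63 ± 0.809. NT5E (CD73), which makes extracellular adenosine, rose from 26.3 ± 4.03 to 67.1 ± 21.3, and MIR4527HG, a microRNA host transcript, from 1.69 ± 0.717 to 22.2 ± 3.99. In edgeR's quasi-likelihood test the log2 fold change was -4.48 for MSN (SE 0.19, adjusted p = 9.7e-06), -2.43 for NR2F1 (SE 0.15, adjusted p = 0.000127), -2.25 for CYP24A1 (SE 0.22, adjusted p = 0.00169), -2.61 for VIM (SE 0.31, adjusted p = 0.00473), 1.38 for NT5E (SE 0.20, adjusted p = 0.00888) and 3.76 for MIR4527HG (SE 0.32, adjusted p = 0.00128).

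Among the other genes named by the rule, the cAMP phosphodiesterase PDE4B (log2 -5.39), the viral restriction factor APOBEC3G (-3.72), the dopamine receptor DRD1 (-3.73), the homing receptor GPR15 (-5.02) and the homeobox gene MSX2 (-2.38) fell in KO tumours, with edgeR adjusted p values from 0.00138 to 0.00484. Hyaluronan synthase HAS3 (log2 1.63), the cell-cycle kinase CDK6 (1.96), carbonic anhydrase CA2 (1.41), the scaffold protein IQGAP2 (2.57), the anthrax-toxin receptor ANTXR2 (2.35), calbindin 2 (CALB2, 1.44), SUN3 (2.10) and PWWP3B (2.24) rose, with adjusted p from 0.00319 to 0.0396. The cornified-envelope gene SPRR2D had 3 counts over the WT tumours and 514 over the KO tumours, a ratio of 186 (counting interval 63.2 to 903). The pseudogene TPMTP1 had 2 and 78 counts, a ratio of 42.3 (11.3 to 355). AC245884.3 had 32 counts in WT and 1 in KO tumours, a ratio of 29.5 (4.93 to 1203). MIR27B had 25 and 0 counts, so at least 7.69-fold lower in KO over a floor of 3 counts for the group. Such intervals and floors cover counting error only. MIR27B lies inside AOPEP and MIR635 (log2 -3.70, edgeR adjusted p = 0.0202) inside WIPI1, while HAS3 overlaps CHTF8 and AC245884.3 overlaps LENG8-AS1 on the opposite strand. The source of reads at these genes is therefore uncertain.

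By edgeR, 895 of 13617 genes tested differed between the genotypes (446 higher and 449 lower in KO tumours), of which 72 were at least 2-fold higher and 185 at least 2-fold lower. With values rescaled to TPM the count was 260, with 34.6% higher against 49.8% in the main scaling. Leaving out 1 tumour gave 29 genes without WT tumour 1, 152 without WT tumour 2, 76 without WT tumour 3, 77 without KO tumour 1, 2076 without KO tumour 2 and 483 without KO tumour 3. Of the 24 genes named by the rule, MIR4527HG, HAS3, MSN, PDE4B, NR2F1, MSX2, APOBEC3G, CYP24A1, VIM, GPR15 and DRD1 were called in each alternative tried. Leaving out a tumour cost 7 of the 24 calls without KO tumour 1, 5 without KO tumour 3, 10 without WT tumour 1, 4 without WT tumour 2 and 5 without WT tumour 3, and no sign turned.

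The genes in this paragraph were picked from the calls after their values were seen, and no group is tested through them. The colon and liver regulator HNF4A fell by 3.64 (log2, edgeR adjusted p = 0.00169), from an FPKM of 1.29 ± 0.250 to 0.0933 ± 0.0306. E-cadherin (CDH1), the adhesion protein of epithelia, fell by 1.63 (adjusted p = 0.0118), the receptor NOTCH3 by 2.2 (adjusted p = 8.7e-05), the drug exporter ABCC3 by 1.92 (adjusted p = 0.00489), the Wnt effector TCF7L2 by 0.94 (adjusted p = 0.00778) and the matrix protein SPARC by 2.92 (adjusted p = 0.0239). The adhesion molecule ICAM1 rose by 1.85 (edgeR adjusted p = 0.00982), the Wnt antagonist NOTUM by 1.51 (adjusted p = 0.0146) and the repressor ZBTB18 by 1.60 (adjusted p = 0.00840). The ligands EREG and AREG fell by 0.98 and 0.59, as did the factor ETV1, while the phosphatase DUSP6, on chromosome 12, rose by 0.86 (edgeR adjusted p 0.0256, 0.0434, 0.00888 and 0.0214). Of 24 measured genes of MAPK output, 4 rose and 4 fell (5 and 4 adjusted over the list alone), and camera did not call the list (adjusted p = 0.819).

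Of 40 measured genes of oxidative phosphorylation encoded in the nucleus, 10 rose and 0 fell in KO tumours by edgeR (20 rose adjusted over the list alone), against 6.57% of all genes called either way. Camera called the list with a preset correlation of 0.01 (adjusted p = 9.0e-11) and not otherwise (adjusted p = 0.755 with an estimated correlation). Its median log2 fold change was 0.41, which by tumour was 0.32, 0.68 and 0.24. The called members included NDUFA9 of complex I (0.90, edgeR adjusted p = 0.00977), COX6A1 of complex IV (0.71, adjusted p = 0.0192), UQCRQ of complex III (0.78, adjusted p = 0.0278) and ATP5F1B of the ATP synthase (0.75, adjusted p = 0.0299). NDUFA9, COX6A1 and ATP5F1B lie on chromosome 12. Of 34 G2/M genes 6 rose (13 adjusted over the list alone; median 0.32), among them PTTG1, CDK1, KIF2C and CENPA. Of 35 G1/S genes 3 rose, a share near that of all genes (4 adjusted over the list alone; median 0.33), namely PRIM1, which lies on chromosome 12, CDC25A and CCNE1. Camera called both cell-cycle lists with the preset correlation (adjusted p = 3.8e-07 and 4.9e-06) and neither otherwise (adjusted p = 0.755 each with an estimated correlation). Of 21 collagen and matrix genes (median -0.63), 5 fell and 1 rose (10 and 1 adjusted over the list alone), with COL6A1 down by 1.04, HSPG2 by 1.56 and TIMP2 by 1.10 and TIMP1 up by 0.72. That list too was called with the preset correlation (adjusted p = 0.000273) and not otherwise (adjusted p = 0.755 with an estimated correlation). Hypoxia genes had a median of -0.47, with PPFIA4 and PFKFB4 called of 29 by edgeR, a share near that of all genes (2 adjusted over the list alone). Interferon-response genes had a median of -0.41, with IRF9 called of 33, a share below that of all genes (0 adjusted over the list alone, 4 at an unadjusted p under 0.05).

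With the preset correlation, camera called these 6 lists of 33 tested, with adjusted p = 0.000143 for hypoxia and 0.00193 for interferon (adjusted p = 0.833 each with an estimated correlation). So 0 lists held with an estimated correlation, and 0 were at an unadjusted p under 0.05 there, against 13 with the preset correlation. Fry's PValue tests whether a list moves one way on balance, and it called 0 lists (7 unadjusted). Its mixed test, for change in either direction, called 22. Without KO tumour 2, 26 of 32 interferon genes (median -1.12) and 17 of 29 hypoxia genes (median -0.68) were lower in KO tumours by edgeR, as were 12 of 21 collagen and matrix genes (1 higher), while 10 of 34 G2/M genes, 4 of 35 G1/S genes and 14 of 40 oxidative phosphorylation genes were higher. Camera then called 10 lists with the preset correlation, while the lowest adjusted p over the lists was 0.642 with an estimated correlation and 0.0835 by fry. These member counts were chosen after the values were seen. KO tumour 2 was the only KO tumour with the interferon list above WT (0.54), and its hypoxia list lay nearest to WT (-0.05). Leaving it out therefore favours lower values in both lists and is no separate support for them. That fit also called 2076 genes in all, in place of 895.

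**Figure D2:**
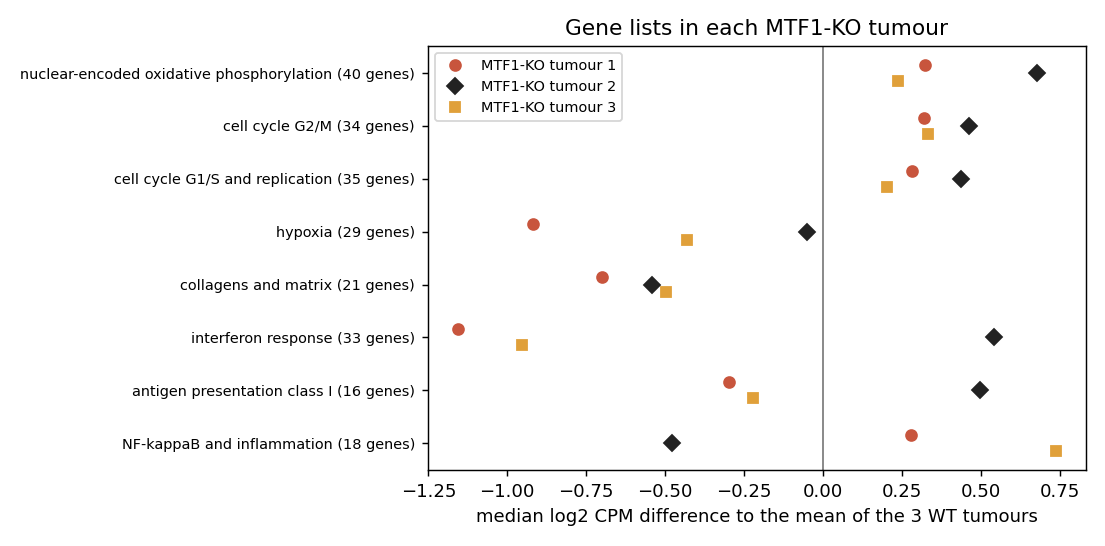
Median log2 CPM difference of each KO tumour from the mean of the 3 WT tumours, for 8 gene lists, 1 point per KO tumour. Oxidative phosphorylation and cell-cycle lists were above 0 in each KO tumour, while the interferon list lay at -1.16, 0.54 and -0.95 in KO tumours 1, 2 and 3.

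Genes of chromosome 12, looked at after the fold changes were seen, were higher in KO tumours as a group. Of 774 tested, 131 rose and 11 fell by edgeR, 16.9% higher against 2.45% of genes elsewhere (Fisher's exact test, one-sided, odds ratio 8.10, adjusted p = 8.07e-58 over chromosomes, where genes are not independent replicates). Their median log2 fold change was 0.29, a 1.22-fold rise, against -0.12 to 0.07 for the other chromosomes. By tumour it was 0.36, 0.11 and 0.41 in KO tumours 1, 2 and 3, and it was 0.0095 between the cultured libraries. In KO tumour 2 chromosome 12 did not stand out, since chromosomes 8 (0.156), 4 (0.116) and 5 (0.112) lay higher. With tumours as the unit, the median log2 level of chromosome 12 genes (each gene against its mean over the 6 tumours) minus that of other genes was higher in each of the 3 KO tumours (-0.036 to 0.285) than in the WT tumours (-0.181 to -0.140), at a two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give. Camera gave adjusted p = 1.7e-10 for the chromosome, and adjusted p = 0.767 with an estimated correlation. Without these genes, 713 genes and 6 lists were called between the tumours.

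**Figure D3:**
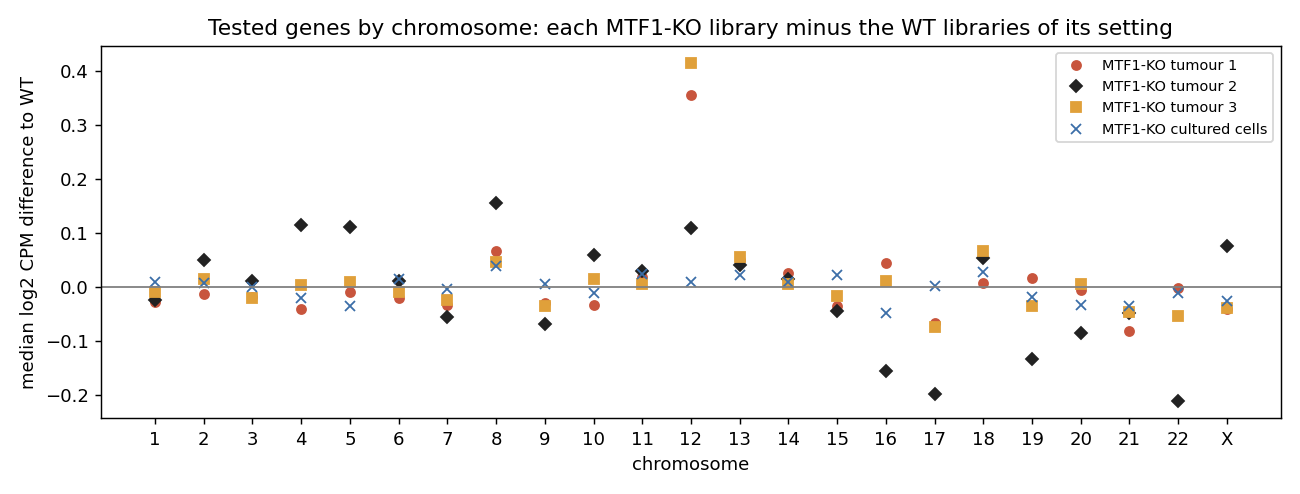
Median log2 CPM difference from WT of the tested genes of each chromosome, 1 point per KO tumour and 1 for the cultured KO library. Chromosome 12 stood at 0.36, 0.11 and 0.41 in the KO tumours and at 0.0095 in the cultured cells. In KO tumour 2 chromosomes 8 (0.156), 4 (0.116) and 5 (0.112) lay above it.

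In culture, 1 KO library was set beside 1 WT library, so these differences have no replicate check and no test. MSN was 50.9-fold lower in the KO library (FPKM 44.8 in WT, 0.88 in KO), CYP24A1 10.4-fold lower (9.77 and 0.94) and NR2F1 5.90-fold lower (21 and 3.55). PDE4B had 1287 counts in WT and 0 in KO cells, so at least 423-fold lower. The EGF-receptor ligands EREG (148 and 8.96) and AREG (81.5 and 10.1), the Wnt ligand WNT16 (16.8 and 0.65), the protein kinase A subunit PRKACB (42.2 and 5.99) and its inhibitor PKIB (24.7 and 4.14) were also lower. MIR4527HG (2.37 and 33.7), the sialic-acid enzyme GNE (5.51 and 32.2), the long non-coding RNA UCA1 (12.95 and 72.2), the adhesion molecule NCAM1 (0.46 and 6.71), the transcription factors FOXQ1 (0.32 and 5.92) and ZBTB18 (6.60-fold), and the surface protein PSCA (0.49 and 7.59) were higher in KO cells. So were the alkaline phosphatases ALPG and ALPP, near-identical copies whose reads cannot be told apart with certainty. RNU7-20P (0.99 and 8.03) overlaps EZH2, and SNORD62A (11 counts in WT and 0 in KO, at least 3.61-fold lower) lies inside PRRC2B, so their reads are uncertain. On the opposite strand, PSCA overlaps JRK (mean FPKM over the libraries 1.91 and 3.11) and GNE overlaps CLTA, so these are uncertain too. In all, 408 of 12886 genes differed by at least 2-fold on the log2(FPKM + 1) scale, 265 higher and 143 lower in KO cells. With pseudocount 0.1 the count was 822, 559 higher and 263 lower.

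The lists of the cultured KO library were placed among random lists of equal size and level. The percentile covers the drawing of genes only, treats members as independent and has no replicate behind it, so it is no test of a change. All 35 G1/S genes were lower (median log2 -0.32, below each of 10000 random lists), as were 30 of 34 G2/M genes (median -0.16, percentile 0.69). The medians of 14 lists were higher than in at least 99.5% of random lists. These were colon differentiation (0.92, 6 of 7 higher), the endothelium and pericyte list (0.49, 6 of 7), mesenchymal genes (0.24, 14 of 15), lysosome and autophagy (0.22, 24 of 27), glycolysis (0.19, 16 of 21), TGF-beta targets (0.58, 14 of 15), collagens and matrix (0.39, 17 of 20), epithelial genes (0.36, 27 of 30), Wnt targets (0.45, 15 of 19), immediate early genes (0.35, 21 of 25), class I antigen presentation (0.34, 12 of 15), interferon response (0.29, 21 of 28), hypoxia (0.30, 22 of 27) and the 13 mitochondrially encoded genes (0.40, 13 higher). The 7 measured members of the endothelium and pericyte list were ESAM, EGFL7, RGS5, CSPG4, MCAM, NOTCH3 and DES. Its members PECAM1, CDH5, VWF and KDR were at an FPKM of at most 0.13 in culture, so no endothelial change is shown. Of the 895 genes called between the tumours, 418 (46.7%) had the same sign in the cultured libraries, against 45.6% of genes not called. Where a called gene also differed by at least 2-fold in culture, 33 had the same sign and 6 the opposite.

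Tumours were set against cultured cells of either genotype to ask what growth in the mouse changed. In the labels, the setting goes with the RNA extraction method, so the share of each cannot be told. Mouse reads counted at human genes could occur in the tumours only, and no step that separates them is given, so their share is unknown too. Interferon-induced genes were much higher in tumours. IFI27 had an FPKM of 47.6 ± 31.1 (SD, n = 6) against 0.36 and 0.72 in WT and KO cells, the antiviral tether BST2 68.8 ± 60.0 against 0.84 and 1.58, and IFI6 344 ± 249 against 16.8 and 22. The polyamine enzyme SAT1 (691 ± 172 against 79.1 and 64.4), the glucose transporter SLC2A3 (18.7 ± 10.8 against 0.82 and 1.36), the hypoxia-induced lipase inhibitor ANGPTL4 (35.2 ± 12.2 against 2.03 and 4.73) and NT5E (46.7 ± 26.2 against 5.20 and 4.07) were higher too. The mannosidase MAN1A1 (14.3 ± 5.27 against 123 and 174), the retinoic-acid enzyme ALDH1A3 (11.4 ± 5.77 against 52.5 and 135) and the stress cytokine GDF15 (36.6 ± 5.23 against 110 and 179) were lower. In edgeR's test the log2 fold change was 6.51 for IFI27 (SE 0.90, adjusted p = 0.00125), 5.88 for BST2 (SE 1.15, adjusted p = 0.00544), 3.27 for SAT1 (SE 0.30, adjusted p = 0.000168), 3.06 for NT5E (SE 0.38, adjusted p = 0.000711), -3.49 for MAN1A1 (SE 0.25, adjusted p = 5.8e-05) and -1.95 for GDF15 (SE 0.17, adjusted p = 0.000126). Interferon genes varied between tumours, and IFI27 was at 99.55 in KO tumour 2 and at 18.5 and 17.5 in KO tumours 1 and 3.

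The other named genes that rose in tumours were IFI6, IFITM1, IFI44, SLC2A3, ANGPTL4, PMEPA1, AC107308.1 and SNORA31 (log2 3.44 to 5.76, edgeR adjusted p from 0.000126 to 0.0104). SNORA31 had 0 counts in WT cells, 2 in KO cells and 123 in the tumours, a ratio to both cultures of 23.5 (counting interval 6.38 to 196), and did not pass without the WT cells; it lies inside TPT1, and AC107308.1 inside HMGA2, so both are uncertain. ADGRF1, ALDH1A3, GATA2, CEMIP, CCN3, CLU, FGF19, EHF, SECTM1 and MIR4442 fell (log2 -5.38 to -2.07, adjusted p from 5.8e-05 to 0.0246); MIR4442 lies inside TOP2B, IFITM1 overlaps IFITM2 on the same strand (mean FPKM 37.1 and 42.9), and CEMIP overlaps MESD (7.03 and 12.4) and GATA2 overlaps GATA2-AS1 on the opposite strand, so these are uncertain too. By edgeR 3629 of 14720 genes differed, 1696 higher and 1933 lower in tumours, of which 1103 and 323 by at least 2-fold. With TPM, which lowered the median of all genes by log2 -0.21 relative to the main scaling, 4360 genes were called, 22.4% of them higher against 46.7%. The count was 1126 without the WT cells, 1804 without the KO cells, 2328 without WT tumour 1 and 5824 without KO tumour 2. Of the 24 named genes, 16 were called in each alternative tried, 7 calls were lost without the WT cells and 4 without the KO cells, and no sign turned.

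Many members of several gene groups differed between culture and tumour, in lists that camera called with the preset correlation and not with an estimated one (lowest adjusted p 0.50 over 35 lists). Of 33 interferon genes 22 rose (28 adjusted over the list alone; median log2 1.33), of 25 immediate early genes 13 (16; median 0.85), led by JUN (1.85), of 19 NF-kappaB genes 10 (12; median 1.40), of 16 antigen-presentation genes 7 (11; median 0.75) and of 53 ribosomal protein genes 19 (30; median 0.60), all with 0 lower in edgeR's test. The immediate early and ribosomal protein lists were fixed as quality lists, so their rise cannot be assigned to growth in the mouse. Of 29 hypoxia genes 13 rose and 1 fell (16 and 1 adjusted over the list alone; median 0.89), with PDK1 up by 2.2, ADM by 2.18 and VEGFA by 1.0. Of 35 G1/S genes 20 were lower (23 adjusted over the list alone; median -0.59), with MCM2 down by 1.10, and of 34 G2/M genes 19 (25; median -0.51). Of 23 NRF2 targets, which guard against oxidants, 15 fell (15; median -0.76), with NQO1 down by 1.84 and GCLM by 1.68, and 1 member up. Of 16 chaperone genes 9 fell (10; median -0.63).

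By edgeR, MT2A rose in tumours (log2 1.10, adjusted p = 0.0278), as did MT1X (1.75, adjusted p = 0.00199), while MT1E (0.64, adjusted p = 0.0745) and MT1F (0.95, adjusted p = 0.0741) did not pass. MTF1 itself fell by 0.60 (edgeR, adjusted p = 0.0151). Of 18 zinc transporters 5 fell (7 lower and 2 higher adjusted over the list alone), SLC39A14 by 1.0, a share near the 24.7% of all genes called. Of 20 copper genes 2 rose and 2 fell (2 and 2). Of 16 iron genes 3 rose and 6 fell (5 and 7 adjusted over the list alone), the haem oxygenase HMOX1 by 1.78, the ferritin chain FTH1 by 1.44 and the transferrin receptor TFRC by 0.91. As sets, zinc (camera adjusted p = 0.0699), copper (0.797) and iron genes (0.352) did not pass camera with the preset correlation. Fry called the zinc list (adjusted p = 0.0381) and the iron list (0.0137) lower in tumours on balance, and not the copper list (0.515).

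Camera with the preset correlation called 19 of 35 lists between tumours and culture, at adjusted p = 1.4e-11 for interferon (adjusted p = 0.50 with an estimated correlation), 3.1e-09 for ribosomal proteins (0.527), 1.3e-07 for G2/M (0.50), 2.1e-07 for G1/S and for immediate early genes (0.50 each), 1.7e-06 for NRF2 targets (0.50), 3.0e-06 for hypoxia (0.50), 3.6e-05 for NF-kappaB (0.50), 0.000445 for antigen presentation (0.50) and 0.000488 for chaperones (0.50). So 0 held with an estimated correlation (2 at an unadjusted p under 0.05), while fry called 16 and its mixed test 33. The remaining 9 lists, at adjusted p from 0.00441 to 0.0380 (0.50 to 0.540 with an estimated correlation), had 2 to 13 called members each.

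**Figure D4:**
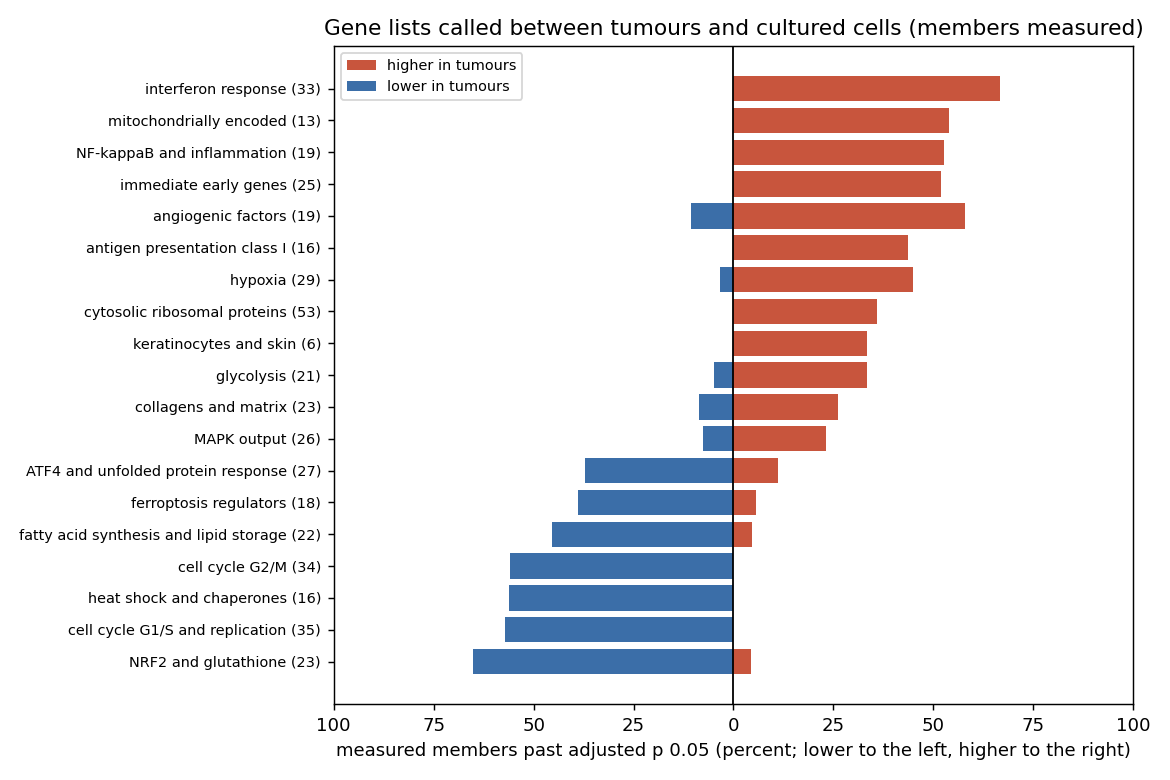
Percent of the measured members of each of the 19 lists called between tumours and culture that passed an edgeR adjusted p of 0.05, higher in tumours to the right and lower to the left. Of the interferon list 22 of 33 were higher, and of the G1/S list 20 of 35 were lower.

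Reads of human genes typical of other cell types were few in the tumours. Host cells in these tumours would be of the mouse, so counts at human genes do not measure how many were present. Leukocyte markers averaged under an FPKM of 1 in 24 of 24 genes, with FCER1G the highest (0.833 ± 0.445, SD, n = 6). The mean was under 1 for 17 of 20 fibroblast genes (highest COL1A1, 6.32 ± 2.87), 14 of 20 endothelium and pericyte genes (EGFL7, 20.2 ± 2.03), 15 of 19 muscle genes (TNNT1, 75 ± 15.8), 10 of 12 adipocyte genes (CFD, 29.9 ± 6.76), 12 of 13 erythroid genes (HBG2, 2.05 ± 0.593) and 10 of 15 keratinocyte genes (KRT10, 22.9 ± 5.59). EGFL7, TNNT1, CFD and KRT10 were also expressed by the cultured cells (12.95 to 57.6 in WT cells). KRT5, a keratin of basal epithelium, rose from 0.07 and 0.03 in culture to 3.03 ± 2.43 in tumours (log2 5.78, edgeR adjusted p = 0.00679).

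The effect of the knockout differed between tumour and culture at 4 genes of 14720 by the interaction test of edgeR (2 higher and 2 lower, against 1572 at an unadjusted p under 0.05). GNE was higher in KO than WT cells (32.2 against 5.51) and lower in KO tumours (2.41 ± 0.0529 against 4.72 ± 0.639, SD, n = 3), a difference in log2 fold change of -3.47 (SE 0.29, adjusted p = 0.00318). GNE overlaps CLTA on the opposite strand, so its source is uncertain. PPFIBP1, a scaffold of focal adhesions on chromosome 12, was at 13.1 in WT and 39.4 in KO cells and at 23 ± 1.97 in WT and 13.8 ± 1.07 in KO tumours (-2.29, SE 0.28, adjusted p = 0.0336). AREG (2.43, SE 0.30, adjusted p = 0.0336) and WNT16 (4.36, SE 0.54, adjusted p = 0.0336) were far lower in cultured KO than WT cells and less so in tumours, where WNT16 did not pass (edgeR, adjusted p = 0.406). EREG (3.07, adjusted p = 0.0528) and FOS (-3.19, adjusted p = 0.0603) did not pass. The lone cultured libraries were assumed to vary like the tumours. Limma on log2(FPKM + 1), the test first planned, called 1 gene, and DESeq2 114. The count was 1 without WT tumour 1, 1 without WT tumour 2, 2 without WT tumour 3, 1 without KO tumour 1, 419 without KO tumour 2 and 1 without KO tumour 3. Of the 4 genes, 0 were called in each alternative tried. GNE kept its call with each tumour left out and lost it with limma at pseudocount 0.1. PPFIBP1 and AREG lost theirs without any 1 tumour but KO tumour 2, and WNT16 without WT tumours 1 or 2 or KO tumours 1 or 3.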

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

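The interaction test at gene level was planned, as were the gene and list counts with each tumour left out. The look at chromosome 12 itself and the interaction test of the lists were chosen only after the results were seen. So were the counts of list members and of chromosome 12 genes without KO tumour 2. The same holds for the tests of the cultured lines, of depth, of a swap and of the genotype labels. It also holds for the tests of quantile normalization on chromosome 12, of the MT2A scaling and of the set of 4 metallothioneins.

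The knockout effect differed between tumours and cultured cells at 4 genes by edgeR's interaction test. The difference in log2 fold change was -3.47 for GNE, -2.29 for PPFIBP1, 2.43 for AREG and 4.36 for WNT16. GNE and PPFIBP1 were higher in KO than WT cells (FPKM 32.2 against 5.51 and 39.4 against 13.1) and lower in KO than WT tumours (2.41 ± 0.0529 against 4.72 ± 0.639 and 13.8 ± 1.07 against 23 ± 1.97, SD, n = 3), and the deficit of AREG and WNT16 in the cultured KO library was smaller in tumours. The same test on lists (camera, preset correlation) called 15 of 35. With an estimated correlation 0 lists passed (3 at an unadjusted p under 0.05, lowest adjusted p 0.232), and fry called 0 (6 unadjusted, lowest 0.0990) and its mixed test 5. The median difference in log2 fold change was 0.72 for G1/S, 0.46 for G2/M, 0.42 for oxidative phosphorylation, 0.46 for chaperones and 0.23 for p53 targets. It was -1.03 for hypoxia, -1.17 for TGF-beta targets, -0.90 for collagens, -1.20 for the endothelium and pericyte list, -0.52 for interferon, -0.93 for immediate early genes, -0.65 for mesenchymal genes, -0.66 for mitochondrially encoded genes, -0.43 for antigen presentation and -0.20 for epithelial genes. Each cultured genotype is 1 library, so a difference between the 2 cultures as grown cannot be separated from the genotype. Leaving out 1 tumour gave 1 gene without WT tumour 1, WT tumour 2, KO tumour 1 or KO tumour 3, 2 without WT tumour 3 and 419 without KO tumour 2.

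Genes of chromosome 12 were higher in KO tumours by a median of 0.29 (log2). After matching on GC content, length and level they were still higher by 0.302, above each other chromosome (highest 0.056). After quantile normalization, which shifts genes by level, their median was 0.187 above the next chromosome (bootstrap 95% range 0.145 to 0.233). That range resampled genes, treats them as independent and leaves out the spread between tumours. The shift of the median in these 6 tumours thus remained after both steps, which do not show that it exceeds the spread between tumours. Scaling in 4 ways with 1 factor per library left at least 0.216, but such a factor moves all genes alike and so tests nothing here. The cultured KO library showed 0.0095, which argues against a difference already present in most of the cultured cells. KO tumour 2 showed 0.11, below chromosomes 8, 4 and 5 in that tumour, so the pattern rests mainly on KO tumours 1 and 3. An extra copy in part of the cells of the KO tumours is a candidate explanation, since the medians of 7 segments of 20 Mb (0.173 to 0.610) lay above the 95th percentile of 145 segments elsewhere (0.118), but the highest of those, on chromosome 8, reached 0.234 (above 3 of the 7), and the 7 were uneven. Whether such a copy goes with MTF1 loss or arose by chance in 1 KO population before injection cannot be separated by 1 KO line, and no DNA was analysed here.

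KO tumour 2 stood apart from KO tumours 1 and 3, and its interferon genes were 2.69-fold higher (median log2 1.43, 31 of 33 higher). Depth does not account for it, since its total of 15.6 M counts was the highest of the KO tumours, and a swap with a WT tumour is argued against by 24 of 33 marker genes that lay nearer to KO tumours 1 and 3. The interferon difference lay far outside random lists matched on GC content, length and level (0.039 to 0.327). These lists treat genes as independent, while the interferon genes had an estimated correlation of 0.73. The range thus speaks to GC content, length and level only and is no test of a change. KO tumour 2 was nearer to the cultured cells than the other tumours were (correlation across genes 0.945 and 0.948, against 0.916 to 0.936), and a different state of that tumour or its handling stays open as a possible explanation, with no group in the labels and no biological explanation tested. Without it, 2076 genes in place of 895 and 10 lists in place of 6 (preset correlation; lowest adjusted p 0.642 with an estimated one) were called between the genotypes, and 263 of 765 genes of chromosome 12 rose. KO tumour 2 had the lowest chromosome 12 median of the KO tumours, so leaving it out is no separate support for that pattern.

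MT2A, MT1E and MT1F were lower in the 1 cultured KO library, and 0 of 4 metallothioneins were called in KO tumours, but the difference between the settings did not pass in edgeR's interaction test (MT2A 1.45, adjusted p = 0.296; MT1E 1.05, 0.379; MT1F 1.12, 0.552; MT1X 0.21, 0.925). Wrong genotype labels are argued against, since of 22 genes at least 4-fold apart between the cultures 10 had all tumours apart on the side of their label and 1 on the other (chance share 5%); an earlier form of this test, with over 70% of genes on the right side in each KO tumour, was missed by KO tumour 3 at 68.2%. The family sum was 477 CPM in the lowest KO tumour against 402 in the lowest WT tumour. This argues against the split of reads among the listed copies, but it cannot address reads that were discarded or assigned outside the family. Scaling stays open, since 4 scalings hardly moved MT2A (lowest log2 0.56) and so hardly tested it. Quantile normalization gave 0.42 (SE 0.26) for MT2A and -0.032 (SE 0.16) for MT1E. Induction in tumours without MTF1, or a knockout that leaves some activity, may each give these values, and neither was tested. The set of 4 measured members did not pass for the difference between the settings with an estimated correlation (p = 0.174, and 0.00331 with the preset one).

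Of the 10 splits of the 6 tumours into 3 and 3, 1 split, the real one, gave as many as 895 genes, and the highest of the others was 4. For lists, 9 of 10 gave as many as the real 6, up to 12. Camera's preset correlation of 0.01 lies far below the estimated correlation of many lists, and whether this or a structure of the tumours gives these counts was not tested. In both cases 10 splits are too few for a share under 0.05.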

How the results depend on the processing

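DESeq2, library totals, the fits without chromosome 12 and TMM scaling in the cultured cells were chosen after the data were seen, limma on log2(FPKM + 1), the planned test for tumours against culture and for the interaction, became an alternative once counts were seen, and the other alternatives here were planned. The cause was not tested for any change named here, except that a fit without a library has fewer samples and one with no filter tests more genes.

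For genes between the tumour genotypes (895), limma on log2(FPKM + 1) called 523, with pseudocount 0.5 474 and with pseudocount 0.1 404. The count was 1869 with no filter on low values, 260 with TPM scaling (90 higher and 170 lower), 3231 with library quality weights and 1762 with DESeq2. Leaving out 1 tumour gave 29 (without WT tumour 1) to 2076 (without KO tumour 2), with 152 and 76 without WT tumours 2 and 3, and 77 and 483 without KO tumours 1 and 3. Of single values in this comparison, 611 kept their sign and side of the threshold, 73 lost the call, 2 gained one and 11 turned sign.

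All sign changes were of metallothioneins that did not pass. MT1E (0.24) was -0.032 with quantile normalization, and -0.032 with the replicate block and quantile normalization. MT1F (0.02) was -0.015 with limma on log2(FPKM + 1), -0.017 with pseudocount 0.5, -0.018 with pseudocount 0.1, -0.030 with TPM scaling, -0.022 with library totals, -0.19 with library quality weights and -0.011 among genes expressed in culture. Leaving out 1 tumour gave -0.18 (without WT tumour 3) to 0.18 (without KO tumour 1), with -0.16 without KO tumour 2.

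For tumours against culture (3629), library quality weights called 2279, WT only 1827 and MTF1-KO only 1161. Leaving out 1 library gave 1126 (without the WT cells) to 5824 (without KO tumour 2), with 1804 without the KO cells and 2328 without WT tumour 1. Of single values, 683 held and 55 lost the call.

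For the interaction (4), limma on log2(FPKM + 1) called 1, pseudocount 0.5 1 and pseudocount 0.1 0 (1534 at an unadjusted p under 0.05). The count was 198 with no filter, 24 at an FPKM of at least 0.1, 1 with TPM scaling, 7 with the robust fit, 248 with library quality weights and 114 with DESeq2. Leaving out 1 tumour gave 1 (without WT tumours 1 or 2, or KO tumours 1 or 3) to 419 (without KO tumour 2), with 2 without WT tumour 3. Of single values, 65 held, 30 lost the call and 13 gained one.

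For lists between the genotypes (6), an estimated correlation gave 0 and fry 0 (0 and 7 at an unadjusted p under 0.05), and leaving out 1 tumour gave 7 to 10 (10 without KO tumour 2, where the lowest adjusted p was 0.642 with an estimated correlation). For lists between tumours and culture (19), an estimated correlation gave 0 (2 unadjusted). In the cultured cells, 822 genes in place of 408 differed by at least 2-fold with pseudocount 0.1, and of single values 15 moved and 65 did not.

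With the replicate number as a block, 909 genes and, at the preset correlation, 10 lists (7 higher and 3 lower, against 3 and 3) were called between the genotypes, with 0 lists at an estimated correlation (0 unadjusted, lowest adjusted p 0.851), and the replicate block with quantile normalization gave 178 genes (67 higher and 111 lower). The correlations across genes of residuals of equal number were -0.035, 0.126 and 0.149, and those of unequal number between the genotypes ran from -0.163 to 0.093. With 3 tumours per genotype, these values cannot tell whether equal numbers marked paired tumours. Simulated 2-fold changes were recovered at 64.2% in the tumour comparison and 1.49% in the interaction, so at this number of libraries a low interaction count does not show that effects are equal.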

Other observations

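The list medians by KO tumour were computed only after the results were seen, and the tests of genes and lists were planned.

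Genes of the p53 response included 3 that rose and 1 that fell in KO tumours, and did not pass as a list (camera adjusted p = 0.0589, and 0.755 with an estimated correlation). With the preset correlation camera called it with the replicate number as a block (adjusted p = 0.0393; adjusted p = 0.851 with an estimated correlation) and without KO tumour 2 (adjusted p = 0.0291; adjusted p = 0.642 with an estimated correlation). By edgeR, TRIAP1 (log2 0.89, adjusted p = 0.0132), the metabolic p53 target TIGAR (1.0, adjusted p = 0.0294), which lies on chromosome 12 as TRIAP1 does, and the nuclease AEN (0.48, adjusted p = 0.0417) rose, and TP53INP1 fell by 0.84 (adjusted p = 0.0199); 6 rose and 1 fell adjusted over the list alone. Among sterol genes the regulator SREBF2 fell by 0.67 (edgeR adjusted p = 0.0299) and EBP and MVK (the latter on chromosome 12) rose by 0.60 and 0.71 (adjusted p = 0.0303 and 0.0470). In the unfolded-protein response SDF2L1 rose by 1.09 (edgeR adjusted p = 0.0293) and the lectin CANX fell by 0.80 (adjusted p = 0.0318). The lactate enzyme LDHB, on chromosome 12, rose by 1.0 (edgeR adjusted p = 0.0113), the apoptosis inducer BCL2L11 fell by 0.82 (adjusted p = 0.0351), and the immediate early factor FOS fell by 1.40 (adjusted p = 0.0111).

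Between culture and tumour, the basement-membrane genes LAMA3 and LAMB3 rose by log2 2.56 and 2.36 (edgeR adjusted p = 0.000963 and 0.00199), as did the protease MMP7 (5.25, adjusted p = 0.00577) and the chemokine CCL20 (7.04, adjusted p = 0.0193). The semaphorin SEMA3C rose by 2.61 (edgeR adjusted p = 5.8e-05), and the Wnt-receptor ligase ZNRF3 fell by 2.2 (adjusted p = 5.8e-05). Serine-synthesis genes PSAT1 and PHGDH fell by 1.5 and 1.15 (edgeR adjusted p = 0.00104 and 0.00204), and the cystine importer SLC7A11 fell by 1.61 (adjusted p = 0.00183). Lipid genes ACSL1, ELOVL6 and ACLY fell by 1.20, 0.93 and 0.86 (edgeR adjusted p = 0.00478, 0.00467 and 0.00570).

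Mitochondrially encoded genes took 7.57% ± 1.07 of counts in WT tumours and 5.95% ± 1.16 in KO tumours (SD, n = 3). By KO tumour, the median log2 difference from WT of the antigen-presentation list was -0.30, 0.50 and -0.22, that of the NF-kappaB list 0.28, -0.48 and 0.74, and that of the hypoxia list -0.92, -0.05 and -0.43, in KO tumours 1, 2 and 3. KRT5, on chromosome 12, was at an FPKM of 6.43, 4.62 and 3.64 in the WT tumours and at 0.36, 2.90 and 0.22 in the KO tumours (edgeR adjusted p = 0.145).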
